A study of Homo sapiens with 9 samples.

How the data were processed

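Biotin-labelled cRNA from 9 RNA samples of RPMI8226 cells, 3 per group, had been hybridised to Illumina HT-12 v4 arrays. The labels spell the line RPMI8266 in one place. Per the labels, the authors used the Illumina TotalPrep kit and Partek 6.6, without stating the normalization. The deposited non-normalized table holds the mean bead intensity of 47323 probes per array on a linear scale, not normalized between arrays, and a detection p-value for each probe and array in steps of 1 in 770. The authors' processed table holds log2 values that matched the quantile-normalized log2 raw intensities within 0.00392.

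The non-normalized table was used. Background was corrected with the normexp model of limma 3.58.1 (R 4.3.3), with the background estimated from the detection p-values and an offset of 16, followed by quantile normalization and log2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probes were kept if detected at p under 0.01 on at least 3 of 9 arrays, which left 16609. Of all probes, 30113 had 1 gene symbol in the platform table, 8 had several and 17202 had none, and 30074 were matched by Entrez ID to a current gene table of GRCh38.p14, used for names alone. Of the kept probes 13024 had a symbol and 3585 did not. The probe with the highest mean stood for each gene, giving 9899 genes. No genome build for probe positions was used, and no positions are given.

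One limma model with group as its term was fitted to all 9 arrays (6 residual degrees of freedom). The tests were two-sided with empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05. Comparisons were GBZ against control, Sal003 against control and Sal003 against GBZ. A gene was counted as undetected in a group when no probe of it was detected on any array of the group, and its fold is then a lower bound set against the lowest detected intensity. With such genes at their bound, 7 of 81 list medians moved, by at most 0.0841. The labels do not state whether replicates were separate cultures, and where they were not, p-values measure the spread between these samples alone.

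A check of each array's deviation from its group mean gave r of 0.238 to 0.538 (median 0.376) for the 9 pairs of arrays with the same replicate number and -0.421 to 0.0670 (median -0.232) for the 18 pairs with different numbers. The numbers were therefore also fitted as a block (4 residual degrees of freedom), and the blocked totals of genes are given beside the main ones. Unless stated, p-values and counts of list members are from the fit without the block. Member counts were never lower with the block. Effects of the compounds were compared by r and covariance across genes against 100 simulations of unchanged groups sharing the controls with independent arrays, and 100 more with an effect for each replicate number, added after the result was seen.

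Before the data were examined, 27 gene lists with 763 members were fixed, of which 717 had a probe with that symbol, together with markers of other cell types, the tests, the alternatives and the rule for naming genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted within each comparison, and with an estimated correlation and with fry. No list passed with an estimated correlation in any comparison, with lowest adjusted p = 0.0682 for GBZ against control, 0.200 for Sal003 against control and 0.0838 for Sal003 against GBZ. That test also rests on few residual degrees of freedom, so a lost call does not by itself show an effect of correlated genes. The aryl hydrocarbon receptor list with Sal003 had the lowest estimated correlation, -0.118, below the preset, yet its camera adjusted p went from 0.00144 to 0.200. Other estimates lay far above the preset: 0.725 for interferon-stimulated genes, 0.483 for ATF4 and CHOP targets and 0.225 for cholesterol genes. For such lists the camera p-values at the preset may be too small. Named genes were PPP1R15A, PPP1R15B, EIF2S1, DDIT3 and ATF4, the 8 largest rises and 8 largest falls per comparison with control whose 3 values all lay outside the control range, 5 of each between the compounds, and up to 3 members of each list that passed and of the ATF4, ER chaperone and plasma cell lists. All 114 called results of named genes had their 3 values outside the range of the 3 values they were compared with. The rule required this of the largest rises and falls, so for them it is no separate evidence. Where 5 or fewer members of a list changed, all are named, and those outside the rule were chosen after their values were seen.

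Alternatives covered the background correction, its offset, the normalization between arrays, the authors' processed values, the filter, the handling of several probes, every probe in place of genes, the arrays in the fit, the variance model, the threshold, the block, the list test and each array left out in turn. Leaving out all arrays of a replicate number, and the block with an estimated correlation, were added after seeing the data. The pipeline was tested on simulated data with 200 of 9899 genes changed. It recovered 11.9% of changes of 0.5 on the log2 scale, 88.1% of changes of 1 and 97.0% of changes of 2, with 8 false calls among 139, 0 of the wrong sign and 0 calls in an unchanged comparison. Kept probes without a gene symbol were tested apart and are not part of the gene counts.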

Results

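Gene expression was measured on Illumina HT-12 v4 arrays in RPMI8226, an established human cell line from multiple myeloma, a cancer of antibody-secreting plasma cells. The 9 arrays formed 3 groups of 3: untreated control cells, cells given 50 µM guanabenz (GBZ) for 24 h, and cells given 20 µM Sal003 for 24 h. Both compounds are named by the study as inhibitors of the phosphatase that removes phosphate from eIF2α, a translation initiation factor. Median raw intensity per array lay between 98.1 and 117.6, and 14865 to 16086 of 47323 probes were detected per array (31.4% to 34.0%). After filtering, 9899 genes were tested. Principal components 1 and 2 held 41.8% and 21.4% of the variance. Values below are log2 fold changes ± SE of the fitted difference between 3 arrays and 3 arrays unless another unit is given. Their precision is limited by the number of arrays.

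The comparison of GBZ with control asked what 24 h of guanabenz did to the cells' transcripts. With GBZ, 24 of 30 interferon-stimulated genes, 14 of 19 cholesterol genes and 7 of 19 NF-κB target genes rose, and 4 of 35 DNA replication genes fell. PPP1R15A, the stress-induced subunit of the eIF2α phosphatase, rose by 1.78 ± 0.19 (adjusted p = 0.00131), and DDIT3, which encodes the stress transcription factor CHOP, by 1.76 ± 0.33 (adjusted p = 0.0163). ATF4, a transcription factor whose translation increases when eIF2α is phosphorylated, had a difference of 0.17 ± 0.18 (adjusted p = 0.636), and EIF2S1, the gene of eIF2α, -0.14 ± 0.19 (adjusted p = 0.723). PPP1R15B, the constitutive phosphatase subunit, had 2 probes detected on at most 2 of 9 arrays and was not tested. Of 32 ATF4 and CHOP target genes tested, 5 rose (ATF3, DDIT3, DDIT4, NUPR1 and PPP1R15A), 0 fell and 27 did not pass, against 7 and 1 adjusted over the list alone. ATF4 and CHOP target genes had a median log2 fold change of 0.32 (camera adjusted p = 0.000424, adjusted p = 0.480 with an estimated correlation). NUPR1, a stress-induced chromatin regulator detected on 2 of 3 control arrays, rose by 1.49 ± 0.35. Of 34 ER chaperone and ER-associated degradation genes tested, 2 rose (DERL3 and DNAJB9), 0 fell and 32 did not pass, against 5 and 0 adjusted over the list alone. ER chaperone and ER-associated degradation genes had a median log2 fold change of 0.24 (camera adjusted p = 9.09e-06, adjusted p = 0.185 with an estimated correlation). The 2 members were DNAJB9 (0.80 ± 0.15), an ER co-chaperone, and DERL3 (0.78 ± 0.14), a component of ER-associated degradation.

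IFNB1, which encodes interferon beta, rose by 2.58 ± 0.37 (adjusted p = 0.00501) and was detected on 1 of 3 control arrays and on all 3 GBZ arrays. IL4I1, a secreted amino acid oxidase, was undetected in control and at least 4.45-fold higher with GBZ. The other largest rises were in the interferon-inducible genes OASL (2.51 ± 0.40, adjusted p = 0.00808), ZBP1 (2.35 ± 0.24, adjusted p = 0.00130), SLFN5 (2.39 ± 0.33) and TRIM22 (2.31 ± 0.52), and in EGR1, an immediate-early transcription factor (2.38 ± 0.19). SLFN5 and TRIM22 were detected on 2 of 3 control arrays and EGR1 on 1 of 3. IL21R, the interleukin-21 receptor, rose by 2.63 ± 0.33 on its tested probe, detected on 7 of 9 arrays, while a second probe detected on all 9 gave -0.23. Of 30 interferon-stimulated genes tested, 24 rose, 0 fell and 6 did not pass, against 28 and 0 adjusted over the list alone. Interferon-stimulated genes had a median log2 fold change of 1.46 (camera adjusted p = 3.76e-23, adjusted p = 0.160 with an estimated correlation). OAS3 rose by 2.29 ± 0.45 and IFIT3 by 2.27 ± 0.44. Of 19 NF-κB target genes tested, 7 rose, 0 fell and 12 did not pass, against 10 and 0 adjusted over the list alone. NF-κB target genes had a median log2 fold change of 0.69 (camera adjusted p = 2.68e-08, adjusted p = 0.0916 with an estimated correlation). Examples were the chemokine CCL3 (1.89 ± 0.17), from a family of near-identical copies, the adhesion receptor ICAM1 (1.46 ± 0.20) and NFKB2 (1.30 ± 0.21). Of 24 immediate-early genes tested, 5 rose (DUSP4, DUSP5, EGR1, JUNB and KLF6), 0 fell and 19 did not pass, against 7 and 0 adjusted over the list alone. Immediate-early genes had a median log2 fold change of 0.29 (camera adjusted p = 8.24e-07, adjusted p = 0.0808 with an estimated correlation). KLF6 rose by 1.29 ± 0.15 and the phosphatase gene DUSP4 by 1.06 ± 0.16.

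Of 19 cholesterol synthesis and uptake genes tested, 14 rose, 0 fell and 5 did not pass, against 17 and 0 adjusted over the list alone. Cholesterol synthesis and uptake genes had a median log2 fold change of 0.97 (camera adjusted p = 5.64e-21, adjusted p = 0.0682 with an estimated correlation). HMGCS1, the synthase at the start of the mevalonate pathway, rose by 2.26 ± 0.13 (adjusted p = 0.000106), MVD, mevalonate diphosphate decarboxylase, by 2.11 ± 0.15 and LSS, lanosterol synthase, by 1.51 ± 0.13. Of 13 fatty acid synthesis genes tested, 6 rose, 0 fell and 7 did not pass, against 8 and 0 adjusted over the list alone. Fatty acid synthesis genes had a median log2 fold change of 0.63 (camera adjusted p = 2.48e-07, adjusted p = 0.0808 with an estimated correlation). ACSS2, which makes acetyl-CoA from acetate, rose by 2.31 ± 0.27, and the fatty acid desaturases FADS2 and FADS1 by 1.17 ± 0.23 and 1.02 ± 0.20. Of 33 autophagy and lysosome genes tested, 10 rose, 0 fell and 23 did not pass, against 16 and 0 adjusted over the list alone. Autophagy and lysosome genes had a median log2 fold change of 0.28 (camera adjusted p = 2.68e-08, adjusted p = 0.0682 with an estimated correlation). The phosphoinositide-binding autophagy gene WIPI1 (1.81 ± 0.40), the lysosomal sialidase gene NEU1 (1.72 ± 0.14) and the autophagy receptor gene SQSTM1 (1.04 ± 0.13) were among them. Of 17 plasma cell identity genes tested, 2 rose (CD38 and TNFRSF13B), 0 fell and 15 did not pass, against 4 and 1 adjusted over the list alone. Plasma cell identity genes had a median log2 fold change of 0.18 (camera adjusted p = 0.00378, adjusted p = 0.286 with an estimated correlation). CD38, a surface enzyme of plasma cells, rose by 2.01 ± 0.29 and the receptor gene TNFRSF13B by 0.75 ± 0.14. Of 28 hypoxia-induced glycolysis genes tested, 4 rose (ANKRD37, BNIP3L, DDIT4 and PFKFB4), 0 fell and 24 did not pass, against 7 and 1 adjusted over the list alone. Hypoxia-induced glycolysis genes had a median log2 fold change of 0.17 (camera adjusted p = 0.00727, adjusted p = 0.330 with an estimated correlation). PFKFB4, an enzyme that controls glycolytic flux, rose by 1.34 ± 0.17, DDIT4, an mTOR inhibitor, by 1.09 ± 0.23 and ANKRD37 by 0.74 ± 0.14. Of 19 histone genes tested, 6 rose, 1 fell (H2BC4) and 12 did not pass, against 7 and 2 adjusted over the list alone. Histone genes had a median log2 fold change of 0.18 (camera adjusted p = 0.0183, adjusted p = 0.286 with an estimated correlation). Without GBZ replicate 3 the histone median was 0.09 and the call ended (camera adjusted p = 0.0976). H2BC5 (1.23 ± 0.24), H2BC21 (1.15 ± 0.27, 2 of 3 control arrays detected) and H2AC25 (0.94 ± 0.21) rose, all members of families of near-identical copies.

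The largest falls with GBZ were in CAMKV (-2.08 ± 0.36, adjusted p = 0.0110), DNAAF3 (-2.05 ± 0.26, adjusted p = 0.00324), a dynein arm assembly factor, KRT6C (-1.92 ± 0.41, a keratin with near-identical copies, detected on 1 of 3 GBZ arrays) and CALML3 (-1.82 ± 0.40). HMOX1, the heme-degrading enzyme heme oxygenase 1, fell (-1.38 ± 0.23, adjusted p = 0.00930), as did the surface protein gene CD7 (-1.38 ± 0.28, detected on 2 of 3 GBZ arrays). PTPRF and CRIP2 were undetected with GBZ and at least 1.505-fold and 1.71-fold lower. Of 35 DNA replication genes tested, 0 rose, 4 fell (CDC45, MCM4, TYMS and UHRF1) and 31 did not pass, against 0 and 9 adjusted over the list alone. With the replicate block 0 rose and 11 fell. DNA replication genes had a median log2 fold change of -0.36 (camera adjusted p = 1.33e-08, adjusted p = 0.155 with an estimated correlation). UHRF1, a factor in copying DNA methylation, fell (-0.79 ± 0.15), as did MCM4 (-0.60 ± 0.12), part of the replicative helicase, and CDC45 (-0.54 ± 0.12). Of 29 ribosome biogenesis genes tested, 0 rose, 2 fell (BOP1 and LYAR) and 27 did not pass, against 0 and 2 adjusted over the list alone. Ribosome biogenesis genes had a median log2 fold change of -0.25 (camera adjusted p = 0.000270, adjusted p = 0.330 with an estimated correlation). The values were -0.59 ± 0.14 for LYAR and -0.52 ± 0.13 for BOP1. Heat shock protein genes numbered 18, of which 0 rose and 0 fell, with 0 and 0 adjusted over the list alone, a median of -0.19 and a camera adjusted p = 0.00808 (adjusted p = 0.155 with an estimated correlation). Proteasome subunit genes numbered 31, of which 0 rose and 0 fell, with 0 and 0 adjusted over the list alone, a median of -0.14 and a camera adjusted p = 0.0205 (adjusted p = 0.545 with an estimated correlation). Without control replicate 3 the proteasome median was -0.09 (camera adjusted p = 0.144), and the call also ended without GBZ replicate 1 or 2. Tubulin genes numbered 11, of which 0 rose and 0 fell, with 0 and 0 adjusted over the list alone, a median of -0.26 and a camera adjusted p = 0.0205 (adjusted p = 0.330 with an estimated correlation). Respiratory chain subunit genes numbered 48, of which 0 rose and 0 fell, with 0 and 0 adjusted over the list alone, a median of -0.06 and a camera adjusted p = 0.0496 (adjusted p = 0.504 with an estimated correlation). No member of these 4 lists passed the test without the block in the comparison of GBZ with control. With the block, 4 heat shock protein, 2 tubulin, 1 proteasome and 0 respiratory chain genes fell.

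The other 10 lists did not pass in the comparison of GBZ with control. Of 7 metallothionein list genes, 0 rose and 0 fell, against 0 and 0 adjusted over the list alone (median -0.42, camera adjusted p = 0.0501). Of 18 p53 target genes, 1 rose (CDKN1A) and 1 fell (DDB2), against 1 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.0575). Of 16 myeloma adhesion and homing genes, 2 rose (CCR1 and CD47) and 0 fell, against 2 and 0 adjusted over the list alone (median 0.18, camera adjusted p = 0.0607). Of 35 mitosis genes, 0 rose and 1 fell (PLK1), against 0 and 1 adjusted over the list alone (median -0.08, camera adjusted p = 0.0835). Of 15 BCL2 family genes, 3 rose (BCL2, HRK and MCL1) and 0 fell, against 3 and 2 adjusted over the list alone (median 0.05, camera adjusted p = 0.222). Of 66 cytosolic ribosomal protein genes, 0 rose and 0 fell, against 0 and 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.263). Of 18 aminoacyl-tRNA synthetase genes, 0 rose and 0 fell, against 0 and 0 adjusted over the list alone (median -0.05, camera adjusted p = 0.686). Of 20 NRF2 target genes, 0 rose and 1 fell (HMOX1), against 2 and 3 adjusted over the list alone (median 0.04, camera adjusted p = 0.806). Of 18 genes of eIF2α kinases, phosphatase subunits and α2 adrenoceptors, 1 rose (PPP1R15A) and 0 fell, against 1 and 0 adjusted over the list alone (median -0.10, camera adjusted p = 0.806). Of 5 aryl hydrocarbon receptor target genes, 1 rose (TIPARP) and 0 fell, against 1 and 1 adjusted over the list alone (median -0.17, camera adjusted p = 0.806). The lists' median, mean and test differed in sign for the eIF2α kinase, NRF2 and aryl hydrocarbon receptor lists.

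In all, 362 genes were higher and 163 lower with GBZ (limma, adjusted p under 0.05), 5.30% of those tested, and 2194 had an unadjusted p under 0.05. Of the 181 genes changed at least 2-fold, 156 were higher and 25 lower, and 17 were undetected on one side. Changes of at least 2-fold numbered 108 without background correction or with the authors' processed values, and lower genes 87 under median scaling. The 3 GBZ values lay outside the range of the 3 control values for 30.0% of genes, where chance gives 10%. With the replicate number as a block, 778 were higher and 539 lower, including the 525 called without the block, the respiratory chain list missed the threshold (adjusted p = 0.0545), and the metallothionein (adjusted p = 0.0163) and p53 (adjusted p = 0.0286) lists passed it, though not with an estimated correlation (adjusted p = 0.337 and 0.158). Leaving out 1 array gave 151 to 438 higher and 35 to 227 lower genes, the lowest without GBZ replicate 1 and control replicate 1, with 118 changed at least 2-fold without GBZ replicate 1. Without all 3 arrays of replicate 1, 5 were higher and 0 lower, in a fit with fewer arrays. Fits of the same size called 40 genes without replicate 2 and 211 without replicate 3. The count therefore depended on which replicate number was left out, not on the number of arrays alone. MCM4, CDC45, LYAR and BOP1 missed the threshold under median scaling.

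**Figure D1:**
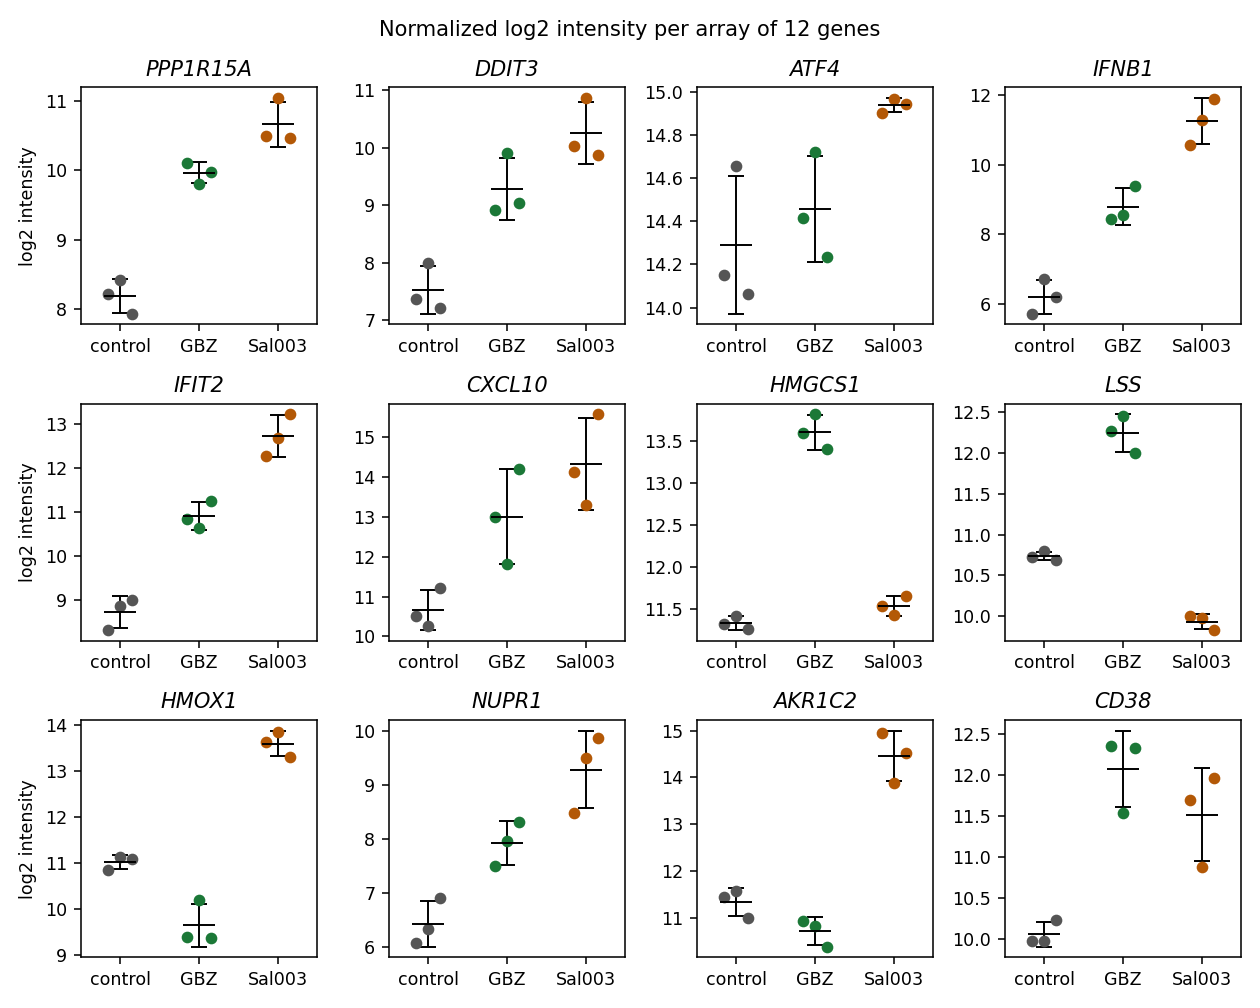
Normalized log2 intensity of 12 genes on each array, with 3 arrays per group as points and the group mean ± SD as bars. PPP1R15A and DDIT3 lie above control in both treated groups, while HMOX1 lies below control with GBZ (-1.38) and above it with Sal003 (2.57).

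The comparison of Sal003 with control asked what 24 h of Sal003 did. With Sal003, 27 of 30 interferon-stimulated genes, 20 of 32 ATF4 and CHOP target genes and 9 of 20 targets of NRF2, a regulator of the oxidative stress response, rose, and 18 of 35 mitosis genes fell. PPP1R15A rose by 2.48 ± 0.19 (adjusted p = 7.03e-05), DDIT3 by 2.73 ± 0.33 (adjusted p = 0.00100) and ATF4 by 0.65 ± 0.18 (adjusted p = 0.0350). Without the filter on detection, ATF4 missed the threshold (adjusted p = 0.0578). EIF2S1 had a difference of 0.09 ± 0.19 (adjusted p = 0.779), and PPP1R15B was not tested. Of 32 ATF4 and CHOP target genes tested, 20 rose, 0 fell and 12 did not pass, against 23 and 0 adjusted over the list alone. ATF4 and CHOP target genes had a median log2 fold change of 0.96 (camera adjusted p = 2.46e-13, adjusted p = 0.271 with an estimated correlation). NUPR1 rose by 2.85 ± 0.35, with 2 of 3 control arrays detected. Of 18 aminoacyl-tRNA synthetase genes tested, 3 rose (FARSB, SARS1 and WARS1), 1 fell (QARS1) and 14 did not pass, against 7 and 1 adjusted over the list alone. With the replicate block 9 rose and 2 fell. Aminoacyl-tRNA synthetase genes had a median log2 fold change of 0.34 (camera adjusted p = 0.0106, adjusted p = 0.407 with an estimated correlation). WARS1 (1.21 ± 0.17) and SARS1 (0.96 ± 0.17) charge tRNA with tryptophan and serine. FARSB (0.62 ± 0.14) rose on its tested probe, while its other probe had the opposite sign and the mean of both gave 0.18 (adjusted p = 0.353). Of 34 ER chaperone and ER-associated degradation genes tested, 1 rose (DNAJB9), 1 fell (DERL3) and 32 did not pass, against 1 and 1 adjusted over the list alone. ER chaperone and ER-associated degradation genes had a median log2 fold change of 0.08 (camera adjusted p = 0.558, adjusted p = 0.867 with an estimated correlation). DNAJB9 rose by 0.76 ± 0.15. Of 20 NRF2 target genes tested, 9 rose, 0 fell and 11 did not pass, against 12 and 0 adjusted over the list alone. NRF2 target genes had a median log2 fold change of 0.50 (camera adjusted p = 1.3e-06, adjusted p = 0.200 with an estimated correlation). HMOX1 rose by 2.57 ± 0.23 (adjusted p = 0.000166), and the aldo-keto reductases AKR1C2 and AKR1C3, near-identical copies, by 3.12 ± 0.27 and 1.83 ± 0.53. Of 5 aryl hydrocarbon receptor target genes tested, 3 rose (AHR, NQO1 and TIPARP), 0 fell and 2 did not pass, against 3 and 0 adjusted over the list alone. Aryl hydrocarbon receptor target genes had a median log2 fold change of 0.77 (camera adjusted p = 0.00144, adjusted p = 0.200 with an estimated correlation). NQO1, a quinone reductase that is also an NRF2 target, rose by 1.45 ± 0.12, the receptor gene AHR by 0.78 ± 0.16 and TIPARP by 0.77 ± 0.17.

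IFNB1 was the gene with the largest rise by the naming rule (5.05 ± 0.37, adjusted p = 5.98e-05, detected on 1 of 3 control arrays). IFIT2, an interferon-induced RNA-binding protein, rose by 4.01 ± 0.27 (adjusted p = 3.22e-05) and the chemokine gene CXCL10 by 3.67 ± 0.64 (adjusted p = 0.00514). SLC24A1, a sodium/calcium/potassium exchanger, PRPH, the neuronal filament protein peripherin, and BEX2 were undetected in control and at least 11.6-fold, 11.2-fold and 6.75-fold higher. NIBAN1, a stress-responsive gene, rose by 3.54 ± 0.30, and SNORD3C, a copy of the U3 small nucleolar RNA with near-identical copies, by 3.50 ± 0.31. Of 30 interferon-stimulated genes tested, 27 rose, 0 fell and 3 did not pass, against 28 and 0 adjusted over the list alone. Interferon-stimulated genes had a median log2 fold change of 2.04 (camera adjusted p = 3.78e-24, adjusted p = 0.206 with an estimated correlation). OAS3 rose by 3.42 ± 0.45 and IFIT3 by 3.30 ± 0.44. Of 19 NF-κB target genes tested, 7 rose, 0 fell and 12 did not pass, against 9 and 0 adjusted over the list alone. NF-κB target genes had a median log2 fold change of 0.50 (camera adjusted p = 1.16e-06, adjusted p = 0.200 with an estimated correlation). Beside CXCL10, CCL3 (2.97 ± 0.17, a gene with near-identical copies) and CCL5 (2.48 ± 0.30) rose.

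SNAI2, a transcriptional repressor, and KRT6C were undetected with Sal003 and at least 2.43-fold and 2.55-fold lower. GPRC5D, a surface receptor of plasma cells, fell (-2.51 ± 0.43, adjusted p = 0.00481), as did DNAAF11 (-2.58 ± 0.28), each detected on 1 of 3 Sal003 arrays. Further large falls were in LBH (-2.19 ± 0.28), CALML3 (-2.16 ± 0.40, detected on 2 of 3 Sal003 arrays), TUBB4A, a neuronal beta-tubulin (-2.15 ± 0.27), and AFAP1L2 (-2.02 ± 0.14, adjusted p = 4.63e-05). Of 35 mitosis genes tested, 0 rose, 18 fell and 17 did not pass, against 0 and 26 adjusted over the list alone. Mitosis genes had a median log2 fold change of -0.50 (camera adjusted p = 8.13e-10, adjusted p = 0.200 with an estimated correlation). The kinesin gene KIF20A (-1.05 ± 0.27), DLGAP5 (-0.93 ± 0.14) and the mitotic kinase gene PLK1 (-0.88 ± 0.14) fell. Of 35 DNA replication genes tested, 0 rose, 2 fell (TK1 and TYMS) and 33 did not pass, against 0 and 1 adjusted over the list alone. DNA replication genes had a median log2 fold change of -0.14 (camera adjusted p = 0.0200, adjusted p = 0.441 with an estimated correlation). TYMS, thymidylate synthase, fell (-0.72 ± 0.12), as did TK1, thymidine kinase (-0.49 ± 0.14). Of 48 respiratory chain subunit genes tested, 0 rose, 6 fell and 42 did not pass, against 0 and 6 adjusted over the list alone. Respiratory chain subunit genes had a median log2 fold change of -0.26 (camera adjusted p = 5.06e-06, adjusted p = 0.278 with an estimated correlation). SDHA (-0.63 ± 0.13), UQCRB (-0.56 ± 0.14) and NDUFV2 (-0.52 ± 0.11) belong to complexes II, III and I. Of 16 myeloma adhesion and homing genes tested, 1 rose (CD47), 4 fell (CADM1, CD81, CD9 and ITGB2) and 11 did not pass, against 1 and 8 adjusted over the list alone. Myeloma adhesion and homing genes had a median log2 fold change of -0.37 (camera adjusted p = 0.0109, adjusted p = 0.206 with an estimated correlation). The tetraspanin genes CD9 and CD81 fell (-0.95 ± 0.11 and -0.64 ± 0.11), as did the adhesion gene CADM1 (-0.87 ± 0.16).

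Of 19 cholesterol synthesis and uptake genes tested, 1 rose (HSD17B7), 5 fell (DHCR7, EBP, INSIG1, LSS and TM7SF2) and 13 did not pass, against 1 and 7 adjusted over the list alone. Cholesterol synthesis and uptake genes had a median log2 fold change of -0.33 (camera adjusted p = 0.0102, adjusted p = 0.407 with an estimated correlation). INSIG1, which holds back the transcription of sterol synthesis genes, fell (-0.96 ± 0.17), as did DHCR7 (-0.83 ± 0.15), the last enzyme of cholesterol synthesis, and LSS (-0.80 ± 0.13). Of 13 fatty acid synthesis genes tested, 0 rose, 4 fell (FADS2, FASN, SCD and SREBF1) and 9 did not pass, against 0 and 6 adjusted over the list alone. Fatty acid synthesis genes had a median log2 fold change of -0.47 (camera adjusted p = 0.0109, adjusted p = 0.313 with an estimated correlation). SREBF1, a transcription factor of lipid synthesis, fell (-1.50 ± 0.33), as did FADS2 (-1.28 ± 0.23) and FASN (-0.91 ± 0.12), the fatty acid synthase. Of 17 plasma cell identity genes tested, 1 rose (CD38), 4 fell (IKZF1, JCHAIN, MZB1 and TNFRSF17) and 12 did not pass, against 2 and 4 adjusted over the list alone. Plasma cell identity genes had a median log2 fold change of -0.09 (camera adjusted p = 0.488, adjusted p = 0.838 with an estimated correlation). TNFRSF17, the plasma cell receptor BCMA, fell (-1.20 ± 0.24, adjusted p = 0.00887), as did JCHAIN (-0.94 ± 0.13), which joins antibody subunits, and the lymphoid transcription factor gene IKZF1 (-0.79 ± 0.14), while CD38 rose.

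Beside the ER chaperone and plasma cell lists, 13 lists did not pass in the comparison of Sal003 with control. Of 18 heat shock protein genes, 1 rose (HSPA1B) and 0 fell, against 0 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.201). Of 7 metallothionein list genes, 1 rose (MT2A) and 0 fell, against 1 and 0 adjusted over the list alone (median 0.10, camera adjusted p = 0.526). Of 18 genes of eIF2α kinases, phosphatase subunits and α2 adrenoceptors, 2 rose (EIF2AK2 and PPP1R15A) and 0 fell, against 2 and 0 adjusted over the list alone (median 0.03, camera adjusted p = 0.434). Of 18 p53 target genes, 5 rose (AEN, CDKN1A, SESN2, TNFRSF10B and ZMAT3) and 4 fell (DDB2, RRM2B, SESN1 and TP53INP1), against 6 and 4 adjusted over the list alone (median 0.10, camera adjusted p = 0.326). Of 15 BCL2 family genes, 4 rose (BCL2, HRK, MCL1 and PMAIP1) and 1 fell (BCL2L11), against 6 and 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.201). Of 31 proteasome subunit genes, 0 rose and 3 fell (PSMD1, PSMD2 and PSMD3), against 0 and 1 adjusted over the list alone (median -0.05, camera adjusted p = 0.437). Of 66 cytosolic ribosomal protein genes, 0 rose and 0 fell, against 0 and 0 adjusted over the list alone (median -0.03, camera adjusted p = 0.552). Of 29 ribosome biogenesis genes, 0 rose and 0 fell, against 0 and 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.574). Of 28 hypoxia-induced glycolysis genes, 4 rose (DDIT4, HK2, PFKFB4 and VEGFA) and 1 fell (MXI1), against 5 and 3 adjusted over the list alone (median -0.04, camera adjusted p = 0.771). Of 33 autophagy and lysosome genes, 6 rose and 0 fell, against 6 and 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.142). Of 24 immediate-early genes, 1 rose (JUN) and 2 fell (KLF10 and KLF2), against 1 and 2 adjusted over the list alone (median -0.01, camera adjusted p = 0.874). Of 11 tubulin genes, 0 rose and 2 fell (TUBB3 and TUBB4A), against 0 and 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.0913). Of 19 histone genes, 5 rose (H1-2, H2AC18, H2BC12, H2BC5 and H4C8) and 1 fell (H2BC4), against 6 and 1 adjusted over the list alone (median 0.21, camera adjusted p = 0.0876). The median, mean and test differed in sign for the hypoxia and immediate-early lists.

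In all, 799 genes were higher and 699 lower with Sal003 (limma, adjusted p under 0.05), 15.1% of those tested, and 2998 had an unadjusted p under 0.05. Of the 502 genes changed at least 2-fold, 350 were higher and 152 lower, and 79 were undetected on one side. Changes of at least 2-fold numbered 319 without background correction or with the authors' processed values, and lower genes 441 under median scaling. The 3 Sal003 values lay outside the range of the 3 control values for 34.8% of genes, where chance gives 10%. With the replicate number as a block, 1200 were higher and 1234 lower, including the 1498 called without the block. Leaving out 1 array gave 539 to 801 higher and 373 to 683 lower genes, with 373 lower genes without control replicate 2, and leaving out all 3 arrays of replicate 1 gave 222 and 105. TK1, UQCRB and NDUFV2 missed the threshold under median scaling.

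**Figure D2:**
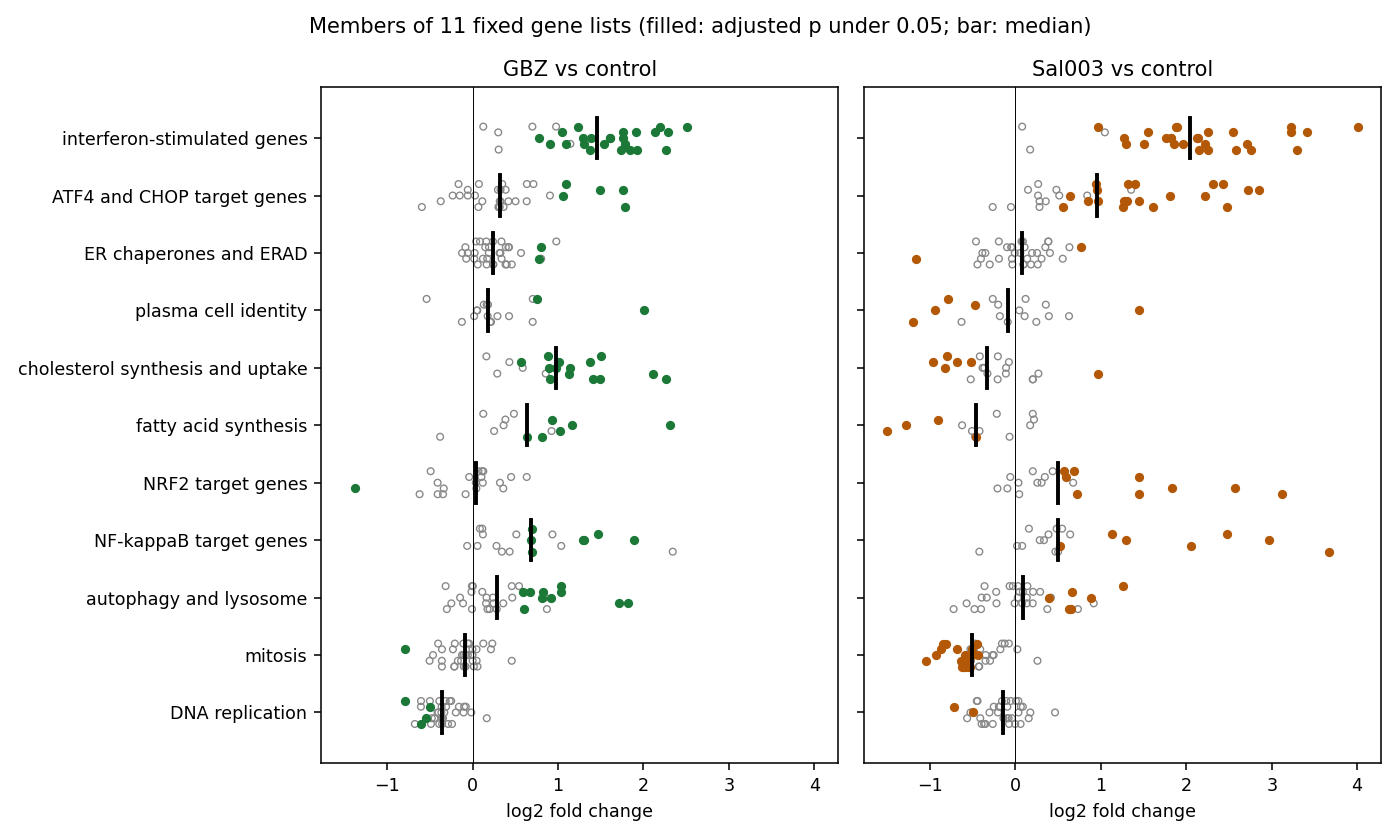
Log2 fold changes of the tested members of 11 fixed gene lists, GBZ against control on the left and Sal003 against control on the right, with filled points at adjusted p under 0.05 and bars at the list median. Cholesterol synthesis genes have a median of 0.97 with GBZ and -0.33 with Sal003, and interferon-stimulated genes 1.46 and 2.04.

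Across the 9899 genes, which are not independent replicates, the log2 fold changes of the 2 compounds had a Pearson r of 0.427. Both share the control arrays, and unchanged groups simulated on shared controls gave a mean r of 0.4997 over 100 simulations. Their covariance was 0.0818 against 0.0183 in the simulations, a difference of 0.0635. These simulations left out the correlation of arrays by replicate number, and simulations that include it gave a covariance of 0.0109, a difference of 0.0709. The sign was the same for 62.1% of genes, against 66.6% in the simulations. The simulated r and share of equal signs are set by the sharing of controls at equal spread. Real effects change both, so observed values below them do not show that the compounds act less alike than unchanged groups. Genes higher with both numbered 161, where independent lists would share 29.2, and genes lower with both 70, against 11.5. The 3 control arrays were too few to split between the compounds, so shared control values enter these excesses. Genes called in opposite directions numbered 27, against 38.7 for independent lists. Of these, 24 were higher with GBZ and lower with Sal003, among them the lipid genes LSS, DHCR7, EBP, TM7SF2, INSIG1, FASN, SCD and FADS2. The other 3 were HMOX1, CD72 and GPAT3, lower with GBZ and higher with Sal003. Genes named here other than HMOX1, LSS, DHCR7, INSIG1, FASN and FADS2 were chosen after their values were seen.

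**Figure D3:**
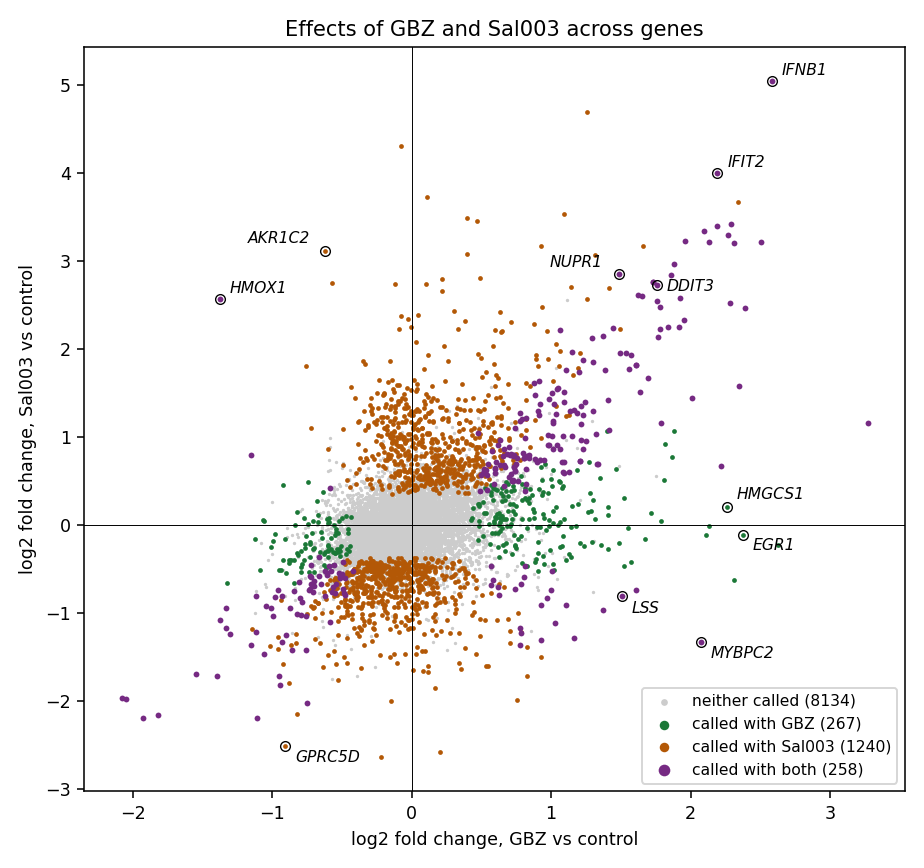
Log2 fold change of each of 9899 genes with GBZ (horizontal) and with Sal003 (vertical), coloured by which comparison called the gene. IFNB1 lies at 2.58 and 5.05, HMOX1 at -1.38 and 2.57, and LSS at 1.51 and -0.80.

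Sal003 was then tested directly against GBZ, at doses that differ. With Sal003, 15 of 19 cholesterol genes and 9 of 13 fatty acid synthesis genes were lower than with GBZ, and 13 of 32 ATF4 and CHOP target genes were higher. PRPH and BEX2 were undetected with GBZ and at least 11.9-fold and 7.15-fold higher with Sal003. HMOX1 was higher by 3.95 ± 0.23 (adjusted p = 1.48e-05), AKR1C2 by 3.74 ± 0.27 (adjusted p = 4.48e-05) and SLC24A1, detected on 1 of 3 GBZ arrays, by 3.44 ± 0.50. Lowest with Sal003 were MYBPC2, a muscle myosin-binding protein gene (-3.40 ± 0.37, detected on 1 of 3 Sal003 arrays), ACSS2 (-2.93 ± 0.27, adjusted p = 0.000176), DNAAF11 (-2.78 ± 0.28, detected on 1 of 3) and DPYSL4 (-2.74 ± 0.26, detected on 2 of 3). IL21R differed by -2.85 ± 0.33 on its tested probe and by 0.15 on the probe detected on all 9 arrays. Of 19 cholesterol synthesis and uptake genes tested, 0 were higher, 15 were lower and 4 did not pass, against 1 and 17 adjusted over the list alone. Cholesterol synthesis and uptake genes had a median log2 fold change of -1.43 (camera adjusted p = 2.8e-17, adjusted p = 0.0838 with an estimated correlation). Of 13 fatty acid synthesis genes tested, 0 were higher, 9 were lower and 4 did not pass, against 0 and 9 adjusted over the list alone. Fatty acid synthesis genes had a median log2 fold change of -0.70 (camera adjusted p = 9.51e-08, adjusted p = 0.0838 with an estimated correlation). Of 33 autophagy and lysosome genes tested, 1 was higher (ATG12), 9 were lower and 23 did not pass, against 1 and 11 adjusted over the list alone. Autophagy and lysosome genes had a median log2 fold change of -0.26 (camera adjusted p = 0.00139, adjusted p = 0.152 with an estimated correlation). Of 16 myeloma adhesion and homing genes tested, 0 were higher, 7 were lower and 9 did not pass, against 0 and 8 adjusted over the list alone. Myeloma adhesion and homing genes had a median log2 fold change of -0.44 (camera adjusted p = 7.72e-05, adjusted p = 0.0838 with an estimated correlation). Of 17 plasma cell identity genes tested, 0 were higher, 5 were lower (JCHAIN, MZB1, SDC1, TNFRSF13B and TNFRSF17) and 12 did not pass, against 0 and 6 adjusted over the list alone. Plasma cell identity genes had a median log2 fold change of -0.33 (camera adjusted p = 0.00175, adjusted p = 0.308 with an estimated correlation).

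Of 34 ER chaperone and ER-associated degradation genes tested, 1 was higher (WFS1), 7 were lower and 26 did not pass, against 2 and 9 adjusted over the list alone. ER chaperone and ER-associated degradation genes had a median log2 fold change of -0.15 (camera adjusted p = 0.00474, adjusted p = 0.348 with an estimated correlation). Of 24 immediate-early genes tested, 1 was higher (JUN), 8 were lower and 15 did not pass, against 1 and 10 adjusted over the list alone. Immediate-early genes had a median log2 fold change of -0.35 (camera adjusted p = 0.000169, adjusted p = 0.144 with an estimated correlation). Of 35 mitosis genes tested, 0 were higher, 9 were lower and 26 did not pass, against 0 and 15 adjusted over the list alone. Mitosis genes had a median log2 fold change of -0.35 (camera adjusted p = 3.7e-07, adjusted p = 0.164 with an estimated correlation). Of 48 respiratory chain subunit genes tested, 1 was higher (CYCS), 3 were lower (NDUFV1, SDHA and UQCRB) and 44 did not pass, against 1 and 2 adjusted over the list alone. Respiratory chain subunit genes had a median log2 fold change of -0.16 (camera adjusted p = 0.00274, adjusted p = 0.351 with an estimated correlation). Of 32 ATF4 and CHOP target genes tested, 13 were higher, 0 were lower and 19 did not pass, against 20 and 0 adjusted over the list alone. ATF4 and CHOP target genes had a median log2 fold change of 0.70 (camera adjusted p = 8.28e-08, adjusted p = 0.308 with an estimated correlation). Of 18 aminoacyl-tRNA synthetase genes tested, 5 were higher (FARSB, HARS1, NARS1, SARS1 and WARS1), 0 were lower and 13 did not pass, against 9 and 1 adjusted over the list alone. Aminoacyl-tRNA synthetase genes had a median log2 fold change of 0.33 (camera adjusted p = 0.00202, adjusted p = 0.308 with an estimated correlation). Of 20 NRF2 target genes tested, 9 were higher, 1 was lower (PGD) and 10 did not pass, against 11 and 1 adjusted over the list alone. NRF2 target genes had a median log2 fold change of 0.41 (camera adjusted p = 3.76e-05, adjusted p = 0.152 with an estimated correlation). Of 5 aryl hydrocarbon receptor target genes tested, 2 were higher (AHR and NQO1), 0 were lower and 3 did not pass, against 4 and 0 adjusted over the list alone. Aryl hydrocarbon receptor target genes had a median log2 fold change of 0.50 (camera adjusted p = 0.00344, adjusted p = 0.105 with an estimated correlation).

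Of 18 heat shock protein genes tested, 4 were higher (CHORDC1, HSP90AA1, HSPA1B and HSPH1), 0 were lower and 14 did not pass, against 7 and 0 adjusted over the list alone. Heat shock protein genes had a median log2 fold change of 0.40 (camera adjusted p = 0.000442, adjusted p = 0.0953 with an estimated correlation). Of 7 metallothionein list genes tested, 1 was higher (MT2A), 0 were lower and 6 did not pass, against 2 and 0 adjusted over the list alone. Metallothionein list genes had a median log2 fold change of 0.56 (camera adjusted p = 0.0140, adjusted p = 0.429 with an estimated correlation). Without GBZ replicate 2 the metallothionein median was 0.29 and the call ended (camera adjusted p = 0.0845). Of 30 interferon-stimulated genes tested, 4 were higher (IFIH1, IFIT2, RSAD2 and XAF1), 0 were lower and 26 did not pass, against 3 and 0 adjusted over the list alone. With the replicate block 16 were higher and 0 lower. Interferon-stimulated genes had a median log2 fold change of 0.53 (camera adjusted p = 5.12e-05, adjusted p = 0.443 with an estimated correlation). Of 29 ribosome biogenesis genes tested, 3 were higher (LYAR, NOP2 and NOP58), 0 were lower and 26 did not pass, against 5 and 0 adjusted over the list alone. Ribosome biogenesis genes had a median log2 fold change of 0.27 (camera adjusted p = 0.000442, adjusted p = 0.348 with an estimated correlation). Of 35 DNA replication genes tested, 3 were higher (CDC45, CHAF1A and POLA2), 0 were lower and 32 did not pass, against 0 and 0 adjusted over the list alone. DNA replication genes had a median log2 fold change of 0.21 (camera adjusted p = 0.0140, adjusted p = 0.429 with an estimated correlation). The metallothionein list includes the zinc exporter gene SLC30A1.

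The other 9 lists did not pass between the compounds. Of 18 genes of eIF2α kinases, phosphatase subunits and α2 adrenoceptors, 4 were higher (ADRA2A, EIF2AK2, EIF2B3 and PPP1R15A) and 0 were lower, against 4 and 0 adjusted over the list alone (median 0.16, camera adjusted p = 0.145). Of 18 p53 target genes, 3 were higher (GADD45A, TNFRSF10B and ZMAT3) and 5 were lower (CCNG1, CDKN1A, RRM2B, SESN1 and TP53INP1), against 4 and 5 adjusted over the list alone (median 0.04, camera adjusted p = 0.786). Of 15 BCL2 family genes, 2 were higher (BID and PMAIP1) and 0 were lower, against 2 and 0 adjusted over the list alone (median 0.07, camera adjusted p = 0.786). Of 31 proteasome subunit genes, 1 was higher (PSMD14) and 0 were lower, against 0 and 0 adjusted over the list alone (median 0.05, camera adjusted p = 0.505). Of 66 cytosolic ribosomal protein genes, 0 were higher and 2 were lower (RPL13 and RPL13A), against 0 and 0 adjusted over the list alone (median -0.05, camera adjusted p = 0.115). Of 28 hypoxia-induced glycolysis genes, 0 were higher and 8 were lower, against 0 and 8 adjusted over the list alone (median -0.08, camera adjusted p = 0.0712). Of 19 NF-κB target genes, 4 were higher (BIRC2, CCL3, CCL5 and NFKBIA) and 3 were lower (CD83, ICAM1 and TNFAIP3), against 4 and 5 adjusted over the list alone (median 0.16, camera adjusted p = 0.573). Of 11 tubulin genes, 1 was higher (TUBA4A) and 1 was lower (TUBB4A), against 1 and 1 adjusted over the list alone (median 0.04, camera adjusted p = 0.877). Of 19 histone genes, 1 was higher (H1-2) and 1 was lower (H2BC21), against 1 and 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.835). The median, mean and test differed in sign for the p53 and tubulin lists.

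In all, 756 genes were higher and 798 lower with Sal003 than with GBZ (limma, adjusted p under 0.05), 15.7% of those tested, and 3155 had an unadjusted p under 0.05. Of the 449 that differed at least 2-fold, 231 were higher and 218 lower, and 64 were undetected on one side. Differences of at least 2-fold numbered 297 without background correction or with the authors' processed values, and lower genes 476 under median scaling. The groups' values did not overlap for 33.7% of genes, where chance gives 10%. With the replicate number as a block, 1363 were higher and 1329 lower, including the 1554 called without the block. Leaving out 1 array gave 431 to 713 higher and 421 to 756 lower genes, both lowest without GBZ replicate 1, and leaving out all 3 arrays of replicate 1 gave 77 and 109.

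Markers of other cell types were few among the tested genes, but several were detected on all 9 arrays. Mean log2 intensity in control was 13.2 for EPCAM, 11.2 for HBA2, 10.9 for CD68, 10.8 for BLK, 9.52 for HBA1 and 8.47 for KRT18. Of the markers fixed beforehand, 2 of 6 B cell, 1 of 7 T cell, 3 of 8 monocyte, 3 of 5 epithelial, 0 of 6 fibroblast and 3 of 7 erythroid genes were tested. With GBZ, CD14 fell (-0.74, adjusted p = 0.0371). FCGR3A was undetected in control and at least 1.41-fold higher with Sal003 (adjusted p = 0.0148), and CDH1 was undetected with Sal003 and at least 1.43-fold lower. BLK (-0.56), EPCAM (-0.49), KRT18 (-0.59), HBA1 (-1.07) and HBA2 (-1.01) fell with Sal003.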

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

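The tests of the interferon, small nuclear RNA and cholesterol patterns were chosen only after those results were seen, while the counts over other splits of the arrays were planned. Groups of 3 arrays were not tested for outlying samples.

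The 2 compounds moved 27 genes in opposite directions, each past the threshold against control. Directly tested, the cholesterol list differed between Sal003 and GBZ by a median of -1.43 and the fatty acid synthesis list by -0.70 (log2, adjusted p = 0.0838 for each with an estimated correlation). HMOX1 differed by 3.95 ± 0.23. Probes without a gene name, which the comparisons left out, held a signal too: of 3585, 82 were called with GBZ (2.29%, against 5.30% of named genes), 435 with Sal003 (12.1% against 15.1%) and 460 between the compounds (12.8% against 15.7%).

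Of 19 cholesterol synthesis genes 14 rose with GBZ (median 0.97), while with Sal003 5 fell, 1 rose and 13 did not pass (median -0.33), and with an estimated correlation neither list passed (adjusted p = 0.0682 and 0.407). Background correction and normalization are argued against, since the Sal003 median closest to 0 over 5 settings was -0.26, with GBZ medians of 0.90 to 0.99. Chance values of the control arrays stay open as the source of the fall with Sal003, which without replicate 1 had a median of -0.20 (adjusted p = 0.0867). A higher sterol level in cells given Sal003 would raise targets of the sterol sensor LXR, whose median was -0.81 with 4 of 5 lower, among them ABCG1 (-1.60) and MYLIP (-1.31). Trapping of GBZ in lysosomes may starve the cell of sterol, and it stays open. By the same reasoning a lack of sterol would lower LXR targets. With GBZ their median was 0.31, with 1 of 5 higher and 0 lower. That is the opposite direction, but 5 genes with 1 call cannot settle it. The lysosome list had a median of 0.28 and lost its call with an estimated correlation (adjusted p = 0.0682). With few residual degrees of freedom that test cannot settle the question.

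Of 30 interferon-stimulated genes 24 rose with GBZ and 27 with Sal003, and with an estimated correlation neither list passed (adjusted p = 0.160 and 0.206). The lowest median over 5 background and normalization settings and both comparisons was 1.31, and without any 1 control array 1.15, which argues against processing and against a single low control array. Joint switching on of interferon and NF-κB transcription may contribute, and the lower NF-κB median of 0.50 leaves it open (adjusted p = 0.0916 and 0.200 with an estimated correlation). That test has few residual degrees of freedom and cannot decide. Infection of the culture was not tested.

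Probes for small nuclear RNAs and U3, made from their own RNA polymerase II promoters, rose with Sal003 in 11 of 13 cases. Their median was 2.66, 2.39 with an undetected member at its bound, and 2.23 to 2.72 over 5 settings. With GBZ 0 rose and 1 fell. The rise with Sal003 was uneven. The 10 probes of U1, U2, U3 and U4, many of them near-identical copies, rose by 2.35 to 3.50. The other 3 lay at 0.26 to 0.64 (median 0.49). A higher yield of RNA without a poly(A) tail, equal for all such RNA, is argued against as the whole source. The median of 45 SNORA and SCARNA probes was 0.11 (7 rose and 1 fell). A share of the rise may come from a higher yield, since 18 of 44 other SNORD probes rose and 2 fell (median 0.44). Likewise, 7 of 10 RNA polymerase III transcripts rose (median 0.85, 0.69 with an undetected member at its bound, and 0.54 to 0.87 over 5 settings). Members of 5 RNA families were called higher, those of U1, U2, U3 and U4 by at least 2.35, which argues against a single cross-hybridising RNA. A change at all genes with such promoters stays open by the calls, since 11 probes rose, 0 fell and 2 did not pass. A change of equal size at all of them is argued against by the 3 probes at 0.26 to 0.64. Slower 3' end processing or decay was not tested. Whether the amount of these RNAs or the share of them that was labelled changed was not tested either.

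For every comparison, 10 splits of its 6 arrays into groups of 3 are possible, too few for a share under 0.05. The real split was the 1 with the largest value for each of the gene counts and list counts. Its genes higher, lower and changed at least 2-fold were 362, 163 and 181 for GBZ, 799, 699 and 502 for Sal003, and 756, 798 and 449 between the compounds, where the highest other split gave 0 (limma). Its lists numbered 17 for GBZ, 12 for Sal003 and 18 between the compounds, where the highest other splits gave 16, 11 and 13. For both comparisons with control, the count of lists at the preset correlation thus hardly sets the real split apart from mixed ones. The 3 other splits that part all replicate pairs gave 0 genes and at most 12, 8 and 13 lists, and the 6 that part 1 pair gave 0 genes and at most 16, 11 and 12 lists. Every other split puts arrays of both groups on each side. A real effect then adds to the spread within the sides, so the 0 genes there cannot speak to chance.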

How the results depend on the processing

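Leaving out all arrays of a replicate number, and the block with an estimated correlation, were added after seeing the data. Over all alternatives 249 counts and correlations stayed within 1.5 times the main value (for correlations, within a fixed distance of it) and 79 moved. For lists, 1182 results kept direction and call and 140 lost the call. For named genes, 2390 results kept both and 343 lost the call. Over the 9 single left-out arrays, 83 of 114 called gene results and 40 of 47 called lists kept the call each time. A stricter threshold loses calls by construction. Fits with arrays left out, and the fit without the filter (20046 genes against 9899), also have less power. Losses from less power were not told apart from dependence on the arrays or probes concerned, with 1 exception. The fits without replicate 1, 2 or 3 had equal numbers of arrays but called 5, 40 and 211 genes with GBZ. The number of arrays alone does not account for those counts. For the other settings the cause was not tested. The correlation between compounds stayed at 0.377 to 0.480.

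Genes changed at least 2-fold numbered 108 (GBZ), 319 (Sal003) and 297 (Sal003 against GBZ) without background correction, and the same with the authors' processed values. Median scaling gave 87, 441 and 476 lower genes. Every probe in place of genes gave 1085 lower and 795 at least 2-fold with Sal003, and 1237 and 746 between the compounds. The replicate block gave 778 higher and 539 lower with GBZ, 1200 and 1234 with Sal003, and 1363 and 1329 between the compounds, ended the GBZ respiratory chain call (adjusted p = 0.0545, with 0.0510 to 0.577 over the 15 settings that ended it at the threshold of 0.05), and changed no other call of a named gene or list except the 2 GBZ lists gained. At adjusted p under 0.01, GBZ had 119 higher, 20 lower and 99 at least 2-fold, Sal003 386 and 220 with 7 lists, and Sal003 against GBZ 250 and 282. With an estimated correlation 0 lists passed for GBZ, 0 for Sal003 and 0 between the compounds, where the preset gave 17, 12 and 18 and fry 14, 18 and 18. The block with an estimated correlation gave 0, 0 and 0. Fry did not call the GBZ lists of ATF4 and CHOP targets (adjusted p = 0.183), proteasome (0.219), ribosome biogenesis (0.0559), hypoxia (0.0726), respiratory chain (0.0840) and tubulins (0.0569), DNA replication with Sal003 (0.0656), or metallothioneins (0.0910), DNA replication (0.0716) and interferon (0.117) between the compounds. Among named genes, NUPR1 with GBZ missed the threshold without background correction (adjusted p = 0.0507), TRIM22 with GBZ and AKR1C3 with Sal003 in the trend model (0.0617 and 0.0878), and 14 of 117 results without the filter.

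A single array left out gave, for GBZ higher genes, 172 without control replicate 1, 182 without control replicate 3, and 151, 178 and 201 without GBZ replicate 1, 2 and 3. GBZ lower genes were 35, 80 and 36 without control replicate 1, 2 and 3, 50, 40 and 86 without GBZ replicate 1, 2 and 3, and 105 without Sal003 replicate 1. GBZ 2-fold genes were 118 without GBZ replicate 1. Sal003 lower genes were 390, 373 and 429 without control replicate 1, 2 and 3. Between the compounds, higher genes were 431 and 443 without GBZ replicate 1 and 2 and 447 and 483 without Sal003 replicate 1 and 3, and lower genes 421 and 441 without GBZ replicate 1 and 2 and 501 without Sal003 replicate 1. Without replicate 1 the Sal003 cholesterol call ended (median -0.20, adjusted p = 0.0867), without replicate 2 DNA replication with Sal003 (0.141), and without replicate 3 tubulins with GBZ (0.0508). Leaving out all of a number gave, for 1, 2 and 3 in turn, 5, 36 and 170 higher and 0, 4 and 41 lower with GBZ, 222, 334 and 469 higher and 105, 173 and 367 lower with Sal003, and 77, 244 and 388 higher and 109, 307 and 475 lower between the compounds. Genes at least 2-fold fell to 5 and 40 with GBZ without number 1 and 2, 281 and 331 with Sal003, and 176 between the compounds without number 1. Single arrays also ended the GBZ calls of the proteasome list (adjusted p = 0.0648 and 0.0942 without GBZ replicate 1 and 2, 0.144 without control replicate 3), tubulins (0.0942 without GBZ replicate 2, 0.0691 without control replicate 3) and histones (0.0976 without GBZ replicate 3). They ended DNA replication with Sal003 (0.231 without Sal003 replicate 2, 0.0642 without control replicate 3), and between the compounds metallothioneins and DNA replication (0.0845 and 0.0829 without GBZ replicate 2). Over both kinds the ranges were 5 to 438 higher, 0 to 227 lower and 5 to 190 at least 2-fold for GBZ, 222 to 801, 105 to 683 and 281 to 505 for Sal003, and 77 to 713, 109 to 756 and 176 to 493 between the compounds, and lists ranged from 14 to 19, 11 to 14 and 17 to 19.

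The sign turned for IL21R when probes had to be detected on all 9 arrays (-0.23 with GBZ and 0.15 between the compounds), since another probe then stands for the gene, and for 2 results that did not pass: EIF2S1 with Sal003 (-0.0823 to 0.282 over left-out arrays, turned without control replicate 2, Sal003 replicate 3 or all of number 3) and, in the direction of its test, the ER chaperone list with Sal003 (medians 0.00689 to 0.104, the test turned without control replicate 3). Probes with raw intensity near background, 14865 to 16086 of 47323 being detected, limit what a fold can show: 17, 79 and 64 of the 2-fold genes had an undetected side.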

Other observations

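Genes in this part were chosen after their values were seen. CDKN1A, the cell cycle inhibitor p21, rose by 2.22 ± 0.15 with GBZ and 0.68 ± 0.15 with Sal003, and the difference between them was -1.54 ± 0.15 (adjusted p = 0.000237). Among regulators of cell death, BCL2 rose by 1.42 ± 0.22 and 1.08 ± 0.22, HRK by 1.25 ± 0.18 and 1.40 ± 0.18, and MCL1 by 0.71 ± 0.12 and 0.81 ± 0.12 with GBZ and Sal003. PMAIP1, the pro-death protein NOXA, rose by 1.90 ± 0.26 with Sal003 and had a difference of 0.50 ± 0.26 with GBZ (adjusted p = 0.301), and the compounds differed by 1.40 ± 0.26 (adjusted p = 0.00721). Interferon lambda genes IFNL1 and IFNL2 were undetected in control and at least 3.06-fold and 1.46-fold higher with Sal003. TNFSF10, the death ligand TRAIL, rose by 3.17 ± 0.55 with Sal003, GBP1 by 2.69 ± 0.45 and LAMP3 by 3.41 ± 0.34, and LAMP3 rose by 2.19 ± 0.34 with GBZ. With GBZ, TNFSF10 and GBP1 had differences of 1.66 ± 0.55 and 1.42 ± 0.45 (adjusted p = 0.111 and 0.102). Neither passed between the compounds (adjusted p = 0.0899 and 0.0839).

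Of the amino acid genes that ATF4 controls, PHGDH rose by 2.43 ± 0.41, ASNS by 1.31 ± 0.22 and the ATF4 inhibitor gene TRIB3 by 1.61 ± 0.27 with Sal003, and each differed between the compounds (1.79 ± 0.41, 0.89 ± 0.22 and 1.24 ± 0.27). INHBE, an activin subunit, rose by 3.07 ± 0.69 with Sal003 (detected on 2 of 3 control arrays). Its difference with GBZ was 1.31 ± 0.69 (adjusted p = 0.299), and the compounds did not differ past the threshold (adjusted p = 0.114). HSPA6, a heat shock gene, was undetected in control and at least 5.12-fold higher with Sal003. That bound holds for the main setting, since the log2 fold change was 1.78 to 2.58 over 5 background and scaling settings. HSPA6 was detected on all 3 GBZ arrays, where it did not pass against control (adjusted p = 0.301). Between the compounds its adjusted p was 0.204. ID3, an inhibitor of basic helix-loop-helix factors, fell (-2.003 ± 0.23), as did ID2 (-0.78 ± 0.21). The immune receptor genes TLR4 (-1.56 ± 0.15, detected on 2 of 3 Sal003 arrays), STING1 (-0.76 ± 0.17) and FCMR (-1.72 ± 0.23) fell with Sal003, while TLR7 rose (1.25 ± 0.35, adjusted p = 0.0390). TLR7 had a difference of 1.13 ± 0.35 with GBZ (adjusted p = 0.0946) and of 0.12 ± 0.35 between the compounds (adjusted p = 0.846). CD6 was undetected with Sal003 and at least 2.27-fold lower. That bound holds for the main setting, since the CD6 log2 fold change was -1.71 to -0.94 over 5 background and scaling settings. SPP1, the bone protein osteopontin, rose with GBZ (1.00 ± 0.13) and fell with Sal003 (-0.74 ± 0.13). The signal of RNU1-1, the U1 small nuclear RNA, rose by 2.35 ± 0.11 with Sal003, RN7SK by 1.31 ± 0.17 and the 5S ribosomal RNA gene RNA5S9 by 2.80 ± 0.17. Of 10 RNA polymerase III transcripts 7 rose (median 0.85, 0.69 with an undetected member at its bound, and 0.54 to 0.87 over 5 background and scaling settings). Whether the amount of these RNAs or the share labelled changed was not tested.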
